A study of Mus musculus with 8 samples.

How the data were processed

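RNA was sequenced from CCR6+ ILC3s of the large intestine, sorted as CD127+ CD90-high cells that lacked T cell, NK cell, B cell and myeloid surface markers, from 4 Zbtb46-sufficient and 4 Zbtb46-deficient mice. Libraries were made with a low-input full-length cDNA kit, per the labels' protocols. The submitters' processing notes list CASAVA 1.8.2, STAR 2.3.0 and the genome build mm10. The counting tool, its annotation, its use of strand and its handling of reads that map to several places are not given in the sources used here. The deposited table holds whole-number read counts per gene under Entrez gene IDs, with no normalization, for 27179 rows and 8 libraries. Of these rows, 25275 were matched to a symbol through the RefSeq gene table of GRCm38.p6, the assembly behind mm10, and the 1904 without one held 0.303% of all counts. Mitochondrial genes were given their mt- symbols, and 7889 rows had 0 counts in all libraries.

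Total counts per library were 25328231, 25903922, 29175568 and 27061294 in sufficient replicates 1 to 4 and 33760743, 26967170, 29603977 and 31823376 in deficient replicates 5 to 8. A count of 0 therefore allows up to 0.0889 to 0.118 CPM, taken as 3 counts of the total. The kit amplifies cDNA from few cells, so depth exceeds the number of sampled molecules and such limits cover counting error alone. Spearman correlations between libraries over tested genes were 0.679 to 0.785 within groups and 0.651 to 0.760 between them, with medians of 0.719 within and 0.728 between.

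Groups were taken from the sample titles. Replicate numbers run from 1 to 8 across both groups, so no number is shared and nothing pairs the mice. The main test, fixed before the data were examined, was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM factors, filterByExpr by group and Benjamini-Hochberg adjusted p under 0.05. CPM values use TMM-scaled library sizes. Standard errors of log2 folds were derived from the F statistic. Single values were compared by exact two-sided permutation tests, whose smallest p is 0.0286 with 4 against 4. Gene lists were tested with limma 3.58.1 by camera with a preset correlation of 0.01, on log2 CPM with a prior count of 2, for lists with at least 3 tested members. Fry and camera with an estimated correlation were alternatives. Camera was adjusted over the 24 lists tested.

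The 28 gene lists covered ILC3 identity, lymphoid tissue inducer cells and CCR6+ ILC3s, cytokines and tissue repair, the RANK axis, class II presentation, chemokine and homing receptors, NF-kB, immediate early genes, interferon response, proliferation, glycolysis, cholesterol synthesis, the clock, ribosomal proteins, mitochondrially encoded genes, the neighbourhood of Zbtb46, sex-linked genes, and markers of dendritic, T, NK and ILC1, ILC2, B and plasma, myeloid, mast, epithelial, stromal and erythroid cells. Named genes were Zbtb46, then up to 12 genes per direction with the largest changes past the threshold whose groups did not overlap and whose higher group had a mean of at least 10 CPM. Where fewer than 6 qualified in a direction, the genes with the smallest p filled it to 6 and were given as not passing. Unnamed gene models were left out. Each list added up to 4 passing members or otherwise the 2 with the smallest p, and 15 key genes were fixed to be named whatever their p. Of these lists and key genes, 1 list and 1 key gene were tested and counted but are not reported here.

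The edgeR and camera steps were tested on simulated counts with the means, library sizes and spread of these genes and 200 genes changed by known folds. Among 8878 genes, 0 of the unchanged genes were called, and among the 1828 genes with a mean of at least 100 CPM, 31.3% of 2-fold, 82.1% of 4-fold and 100% of 8-fold changes were recovered, with 8 unchanged genes called.

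Alternatives fixed in advance were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, limma-voom with sample quality weights, edgeR with robust dispersions, no filter, a filter of at least 5 CPM in at least 4 libraries, 1 surrogate variable (sva 3.50.0), each library left out, and for lists fry, ranks and an estimated correlation. Sex could not be a covariate because all 8 libraries had Xist and almost no Y-linked reads. Added after the data were seen were sets with a mean of at least 100 or 50 CPM, edgeR's newer dispersion method, leaving out replicates 1 and 6, replicates 1, 2 and 7 or replicates 5 and 7, thinning to the smallest total, and covariates for Malat1 and for the number of detected genes.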

Results

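Gene expression was measured by RNA sequencing in group 3 innate lymphoid cells (ILC3s), tissue-resident lymphocytes that secrete interleukin 22. The cells carried the chemokine receptor CCR6 and were sorted from the large intestine of untreated C57BL/6 mice. The 8 libraries came from 8 mice, 1 library per mouse. In 4 of them both copies of Zbtb46, a zinc finger transcription factor best known from classical dendritic cells, were floxed and intact (Zbtb46-sufficient, replicates 1 to 4). In the other 4 a Cre recombinase active in ILC3s removed the floxed part (Zbtb46-deficient, replicates 5 to 8). Library totals ran from 25328231 to 33760743 counts, and 10668 to 14410 genes had at least 1 count. The single comparison of the design asks which transcripts of CCR6+ ILC3s differ when Zbtb46 is deleted. Means are CPM (counts scaled to the library total) ± SD over n = 4 libraries per group, and folds are deficient over sufficient.

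Zbtb46 (Entrez ID 72147, chromosome 2, 181371009 to 181493262 in the RefSeq annotation of GRCm38.p6) had 43.1 ± 34.8 CPM in sufficient and 2.17 ± 2.23 CPM in deficient ILC3s. All 4 deficient libraries lay below all 4 sufficient ones, at 4.82, 0.532, 3.19 and 0.125 CPM against 8.02, 48.8, 88.9 and 26.6 CPM. The fitted log2 fold was -4.31 with a standard error of 1.42, and its adjusted p over all tested genes was 0.885 in edgeR's quasi-likelihood test. Tested alone, the difference had an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give. The RefSeq span of Zbtb46 overlaps those of Lime1, Zgpat, Slc2a4rg-ps and Abhd16b. Whether the counting used strand is not given in the sources used here, so reads of these genes may not be fully separated.

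Across all 8878 tested genes, deletion of Zbtb46 left no single-gene difference that exceeded the spread between libraries after correction. With edgeR, 0 genes were higher and 0 lower at an adjusted p under 0.05, and 364 had an unadjusted p under 0.05, where uniform p values would give 444, a level that no split of the 8 libraries into 4 and 4 reached (highest 440). Of those 364, 186 were higher and 178 lower in deficient ILC3s. DESeq2, run without edgeR's filter on 16714 genes, called 239 higher and 134 lower. Limma-voom with sample quality weights called 0 in each direction with 775 at an unadjusted p under 0.05. Of the 373 genes DESeq2 called, 136 were among those edgeR tested, and 304 (81.5%) had 3 counts or fewer in at least 1 library. Only 8329 genes exceeded 3 counts in deficient replicate 6, so many of the 16714 genes had such a library whether called or not. The groups did not overlap in 387 genes, 4.36% of those tested, where chance gives 2.86%. Low genes varied most from library to library, with a median coefficient of variation of 118% within groups below a mean of 10 CPM and 32.7% at 100 CPM and above. With 1 library per mouse, differences between mice and between library preparations cannot be told apart. On simulated counts with this spread, the same test over all genes recovered 0% of 2-fold, 11.9% of 4-fold and 16.7% of 8-fold changes.

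Among abundant transcripts, deficient ILC3s had more Lgals1 and less Med31, Trmt61b and Snhg15. This set of 1828 genes with a mean of at least 100 CPM was chosen after the data were seen. Lgals1, which encodes the β-galactoside-binding lectin galectin-1 (chromosome 15, 78926725 to 78930465), rose from 233 ± 53.9 to 796 ± 270 CPM, with a fitted fold of 3.59 within this set. Med31, a subunit of the Mediator complex (chromosome 11, 72211724 to 72215592), fell from 1591 ± 462 to 487 ± 105 CPM. Trmt61b, a mitochondrial tRNA methyltransferase (chromosome 17, 71557027 to 71598761), fell from 526 ± 84.8 to 176 ± 31.0 CPM. Snhg15, a noncoding host gene of a small nucleolar RNA (chromosome 11, 6525591 to 6528760), fell from 1400 ± 296 to 548 ± 95.3 CPM. The fitted folds of the 3 lower genes within the set were 0.321, 0.351 and 0.410. The set had scaling factors of its own, while the CPM values use those of all tested genes. In the fit over all tested genes the folds were 3.41 for Lgals1, 0.306 for Med31, 0.335 for Trmt61b and 0.392 for Snhg15. Within the set, edgeR's adjusted p was 0.0124 for Lgals1 and Med31 and 0.0192 for Trmt61b and Snhg15, and in each gene all 4 deficient libraries lay on one side of all 4 sufficient ones. Over all tested genes the adjusted p was 0.191 for Lgals1, Med31 and Snhg15 and 0.174 for Trmt61b. Lgals1 was highest in deficient replicates 5 and 7, at 1150 and 853 CPM against 550 and 629 CPM in replicates 6 and 8, and macrophage and neutrophil markers summed to 335 and 762 CPM in those same libraries, 5 and 7. Most of these sums came from the neutrophil genes S100a8 and S100a9, at 238 and 94.1 CPM in replicate 5 and 316 and 359 CPM in replicate 7. With 1 library left out the counts ranged from 0 to 6 higher and 0 to 15 lower, and edgeR's adjusted p in the abundant set rose past the threshold for all 4 genes without replicate 1, 3 or 5 (0.0516 to 0.142), for the 3 lower ones without replicate 8 (0.0773 to 0.0974), for Snhg15 and Trmt61b without replicate 7 (0.0952) and for Trmt61b without replicate 4 (0.0838). The log2 folds over these settings stayed at 1.63 to 1.99 for Lgals1, -1.82 to -1.49 for Med31, -1.62 to -1.42 for Trmt61b and -1.39 to -1.15 for Snhg15, and without both replicates 5 and 7 no gene passed (adjusted p 0.48 for each of the 4), with a fitted fold of 2.62 for Lgals1.

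**Figure D1:**
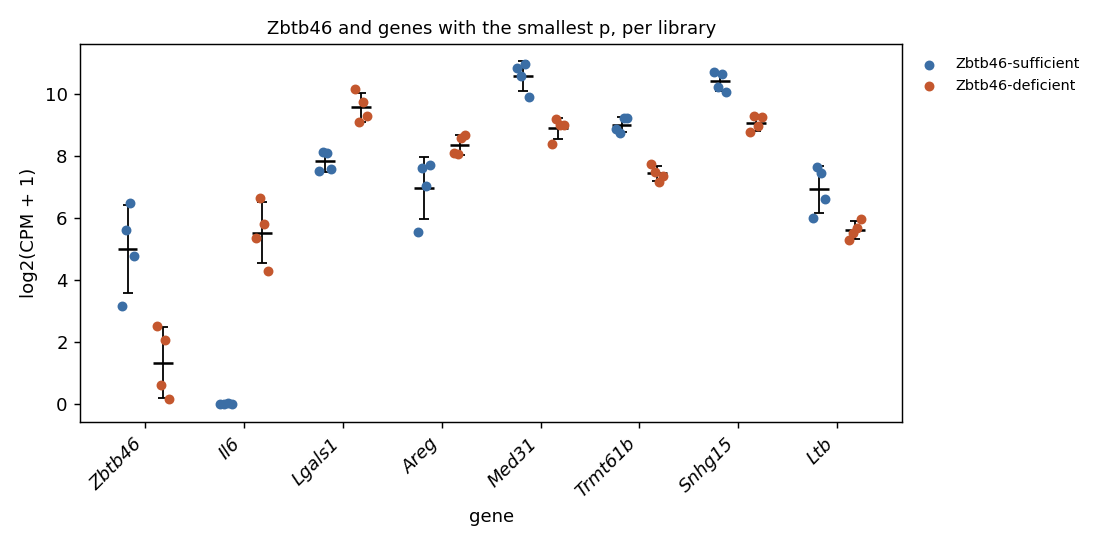
CPM on a log2(CPM + 1) scale for Zbtb46 and 7 named genes in each library, by group. Points are libraries, black lines means and bars ± 1 SD over 4 libraries. Zbtb46, Med31, Trmt61b, Snhg15 and Ltb lay lower, and Il6, Lgals1 and Areg higher, in all 4 deficient libraries than in any sufficient one.

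The remaining genes with the smallest p did not pass the threshold and are given as values. Il6, a proinflammatory cytokine (chromosome 5, 30013114 to 30019975), had 1 count in the 4 sufficient libraries together and 6445 in the deficient ones, which were at 40.2, 101, 55.9 and 18.8 CPM. The scaled ratio of the summed counts was 5290, with a 95% counting interval from 950 to 209000, and edgeR's adjusted p was 0.174. The interval covers counting error alone, and reads without molecular identifiers are not independent molecules. Ift57, Synpo, Susd2 and Stoml2 likewise had 1 to 3 counts over the sufficient libraries and means of 22.7 ± 10.8, 26.2 ± 21.6, 21.5 ± 17.5 and 35.0 ± 25.7 CPM in the deficient ones. In the other direction Aasdh had 23.3 ± 16.1 CPM in sufficient libraries and 1 count over the deficient ones. Cwc25, a splicing factor, had 484 ± 116 against 190 ± 46.9 CPM in sufficient and deficient libraries, and the X-linked gene Xlr4a, which has near-identical copies that may share its reads, 859 ± 105 against 415 ± 127 CPM. The adjusted p of these 7 genes in edgeR lay between 0.472 and 0.515.

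The genes that define ILC3s and their effector products did not differ past the threshold. Of the 15 key genes fixed in advance, Tnfrsf11b did not pass the expression filter and was not tested with edgeR. None of the others passed over all tested genes or adjusted over the list alone with edgeR, and DESeq2 called no key gene. Tnfsf11, encoding the cytokine RANKL, had 3179 ± 391 CPM in sufficient and 3199 ± 221 in deficient ILC3s, a log2 fold of 0.01 with a standard error of 0.161. Its decoy receptor gene Tnfrsf11b had 122 counts in sufficient replicate 2, the library with 1438 CPM of epithelial markers. It had 0 in the other 7 libraries, where a count of 0 allows 0.0889 to 0.118 CPM. Il22 took 1.33% to 2.38% of all counts, with 21240 ± 4647 CPM in sufficient and 15420 ± 2502 in deficient ILC3s. Il17f had 1978 ± 767 against 2796 ± 983 CPM, Il17a 10.7 ± 11.4 against 27.7 ± 23.5, and Csf2 222 ± 80.5 against 258 ± 116. The lymphotoxin genes Ltb and Lta had 133 ± 63.5 against 49.0 ± 9.81 and 51.2 ± 31.4 against 15.6 ± 12.8 CPM. All 4 deficient libraries lay below the sufficient ones in Ltb, and its adjusted p over the key genes alone was 0.119 in edgeR. The chemokine receptor gene Ccr6 had 125 ± 37.8 against 155 ± 125 CPM. Il23r had 2378 ± 689 against 1530 ± 616 CPM, Ahr 124 ± 114 against 48.0 ± 22.0, and Kit 833 ± 235 against 1036 ± 285. The antigen presentation genes Cd74 and H2-Ab1 had 4198 ± 1668 against 2609 ± 1283 and 573 ± 176 against 380 ± 203 CPM.

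**Figure D2:**
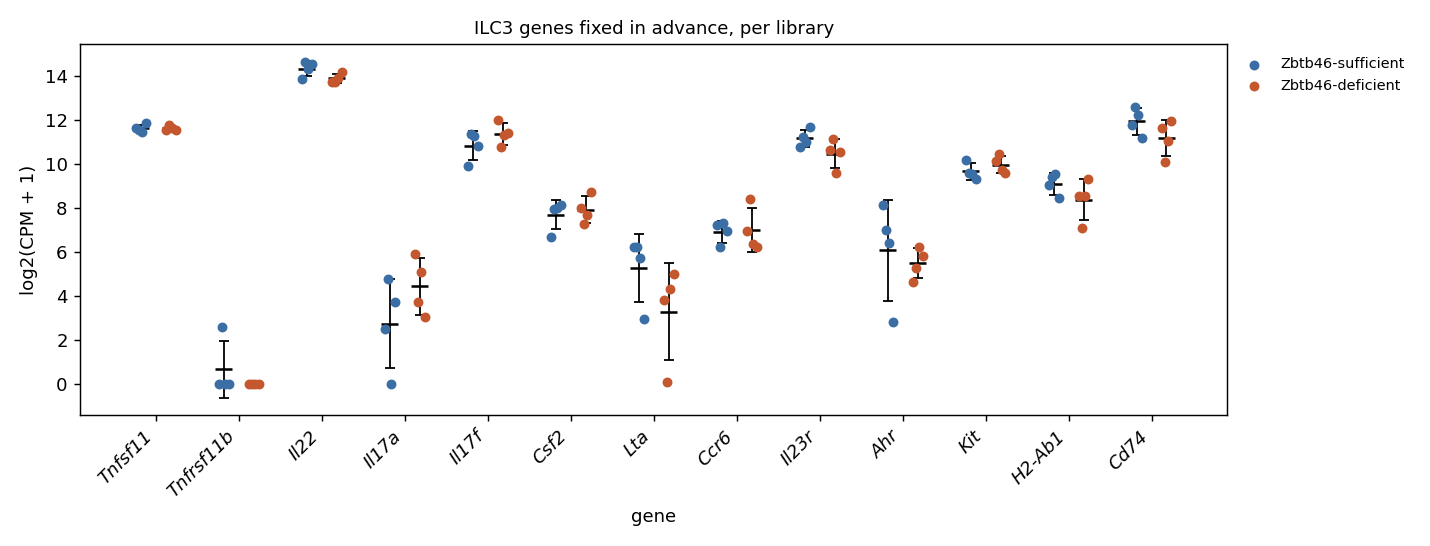
CPM on a log2(CPM + 1) scale for 13 of the key genes fixed in advance, in each library by group. Points are libraries, black lines means and bars ± 1 SD over 4 libraries. The groups overlap in all 13 genes, and Tnfrsf11b has counts in sufficient replicate 2 alone.

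Gene groups were compared through 28 lists fixed in advance, of which 24 had at least 3 tested members. Camera called 0 lists with its preset correlation and 0 with an estimated one, and fry called 0 by its directional test. No member of any list passed the test over all genes or adjusted over the list alone. The 2 lists with an unadjusted camera p under 0.05 both leaned lower in deficient ILC3s. Of 16 NF-kB pathway genes 12 had lower and 4 higher fitted values, with a camera p of 0.0267, adjusted p = 0.327, and adjusted p = 0.728 with an estimated correlation. Birc3, an inhibitor of apoptosis, had 315 ± 78.6 against 187 ± 50.8 CPM, while Cd83 went the other way with 212 ± 78.5 against 393 ± 147. Of 10 genes of lymphoid tissue inducer cells and CCR6+ ILC3s 6 had lower fitted values, with a camera p of 0.0273 and the same adjusted values. The lead members of that list were Ltb and Nrp1, a semaphorin co-receptor with 665 ± 103 against 382 ± 183 CPM.

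The 19 ILC3 identity genes split into 8 with higher and 11 with lower fitted values (camera adjusted p 0.906). Tcf7, encoding the transcription factor TCF-1, had 211 ± 31.6 against 133 ± 21.7 CPM, and Thy1 207 ± 57.5 against 335 ± 87.9. Of 10 tested cytokine and tissue repair genes 6 had higher fitted values (adjusted p 0.906), led by the epidermal growth factor receptor ligand gene Areg with 146 ± 75.4 against 335 ± 71.9 CPM and no overlap between groups. The RANK, RANKL and osteoprotegerin axis had 3 of 5 tested genes higher and an adjusted p of 0.834 with camera's direction down, with Relb at 101 ± 46.7 against 52.4 ± 7.06 CPM and Nfkb2 at 108 ± 31.0 against 66.4 ± 27.7. Class II presentation had 5 of 7 lower (adjusted p 0.779), with H2-Aa at 1419 ± 536 against 979 ± 356 CPM. Chemokine and homing receptors had 7 of 11 higher (adjusted p 0.951), with the integrin gene Itgb7 at 34.9 ± 8.88 against 78.2 ± 15.04 CPM and Cxcr6 at 2409 ± 566 against 1708 ± 570. Immediate early and stress genes had 12 of 17 lower (adjusted p 0.430), with Fos at 485 ± 50.1 against 327 ± 59.2 CPM and Egr1 at 74.9 ± 41.4 against 25.7 ± 9.41.

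Interferon response genes had 8 of 11 lower fitted values (camera adjusted p 0.951), with Gbp2 at 30.9 ± 16.3 against 108 ± 79.7 CPM and Usp18 at 21.9 ± 26.6 against 1.16 ± 1.29. Proliferation genes had 4 of 7 higher (adjusted p 0.906), and Top2a and Ccna2 stayed below 20 CPM in all libraries but deficient replicate 8, which had 55.5 CPM of Top2a. Glycolysis genes had 8 of 13 higher and a camera adjusted p of 0.956, while fry's test for change in either direction gave an adjusted p of 0.0277. Hk2, which phosphorylates glucose, had 3351 ± 749 against 1598 ± 901 CPM, and the pyruvate kinase gene Pkm 34.4 ± 17.6 against 87.2 ± 31.4. Cholesterol synthesis had 8 of 12 higher and an adjusted p of 0.987, with camera's direction down and fry's up. Its lead genes were Sqle with 69.2 ± 23.4 against 175 ± 137 CPM and Fdft1 with 2.67 ± 2.59 against 0.236 ± 0.276. Clock genes had 8 of 12 higher (adjusted p 0.951), with Clock at 30.3 ± 11.4 against 64.9 ± 38.1 CPM and Bhlhe40 at 2196 ± 506 against 1688 ± 622. Ribosomal protein genes had 19 of 24 lower (adjusted p 0.511), with Rps14 at 1780 ± 409 against 1387 ± 351 CPM and Rpl32 at 276 ± 105 against 216 ± 63.7. Mitochondrially encoded genes had 6 of 10 higher (adjusted p 0.906), with mt-Co1 at 1978 ± 438 against 1699 ± 293 CPM and mt-Nd1 at 2945 ± 631 against 3596 ± 1369.

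The genes near Zbtb46 and the sex-linked genes were also followed as lists. Of the tested genes near Zbtb46, 9 of 10 had higher fitted values in deficient ILC3s, with a camera p of 0.0699 and an adjusted p of 0.430. Arfrp1 had 48.5 ± 24.0 against 93.3 ± 79.7 CPM and Gmeb2 39.5 ± 33.9 against 79.0 ± 71.8, with deficient replicate 6 highest in both at 208 and 187 CPM. Xist was present in all 8 libraries, at 325 ± 112 against 205 ± 35.3 CPM, and the 4 Y-linked genes of the sex-linked list stayed at or below 0.228 CPM.

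Markers of other cell types marked single libraries more than groups. Epithelial markers summed to 1438 CPM in sufficient replicate 2 and to at most 28.7 CPM elsewhere, with 724 CPM of the goblet cell mucin gene Muc2 and 388 CPM of Lgals4 in that library. Across groups Lgals4 had 99.96 ± 192 against 7.67 ± 9.39 CPM and Car1 1.62 ± 1.45 against 2.11 ± 4.19. Stromal and endothelial markers summed to 1249 CPM in sufficient replicate 1, with 687 CPM of the matrix proteoglycan gene Dcn, and to 523 CPM in deficient replicate 7, against 74.0 to 228 CPM elsewhere. Of the 4 tested, 3 had lower fitted values (camera adjusted p 0.906), with Dcn at 215 ± 317 against 33.4 ± 66.8 CPM and Pecam1 at 18.8 ± 13.3 against 29.3 ± 15.6. Macrophage and neutrophil markers summed to 335 and 762 CPM in deficient replicates 5 and 7 and to 3.64 to 52.6 CPM elsewhere. Of the 6 tested, 4 had higher fitted values (adjusted p 0.906). The alarmin genes S100a8 and S100a9 had 3.30 ± 4.11 against 140 ± 162 and 3.91 ± 5.71 against 114 ± 169 CPM, and both were under 5 CPM in deficient replicates 6 and 8. Mast cell markers had no tested member and summed to 66.2 CPM in deficient replicate 6, all of it Cpa3. Erythroid markers had no tested member and stayed under 0.3 CPM.

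Lymphoid markers were present in both groups. T cell markers summed to 86.3 to 358 CPM, with 4 of 6 tested members higher in deficient ILC3s (camera adjusted p 0.906). Cd3d had 3.85 ± 7.70 against 7.17 ± 7.83 CPM and Trac 7.29 ± 10.5 against 15.1 ± 26.6. NK cell and ILC1 markers summed to 123 CPM in sufficient replicate 1, 554 to 632 CPM in the other sufficient libraries and 455.5 to 1084 CPM in the deficient ones, highest in replicate 5. Of 5 tested, 3 had higher fitted values (adjusted p 0.906), with the natural cytotoxicity receptor gene Ncr1 at 76.7 ± 85.6 against 254 ± 141 CPM and Ccl5 at 5.21 ± 6.18 against 35.2 ± 49.2. All 4 tested ILC2 markers had lower fitted values (adjusted p 0.906), with Il5 at 4.45 ± 7.16 against 0.614 ± 0.572 CPM and Klrg1 at 9.32 ± 18.3 against 7.36 ± 13.7. B and plasma cell markers had 2 of 3 higher (adjusted p 0.951), with camera's direction down and fry's up. Igkc had 39.0 ± 50.6 against 12.8 ± 15.2 CPM and Jchain 9.27 ± 9.33 against 21.8 ± 27.3. All 4 tested dendritic cell markers had higher fitted values (adjusted p 0.430). Irf8 had 1.78 ± 2.68 against 15.9 ± 7.53 CPM without overlap, and Ccl17 34.1 ± 20.4 against 57.8 ± 47.1.

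**Figure D3:**
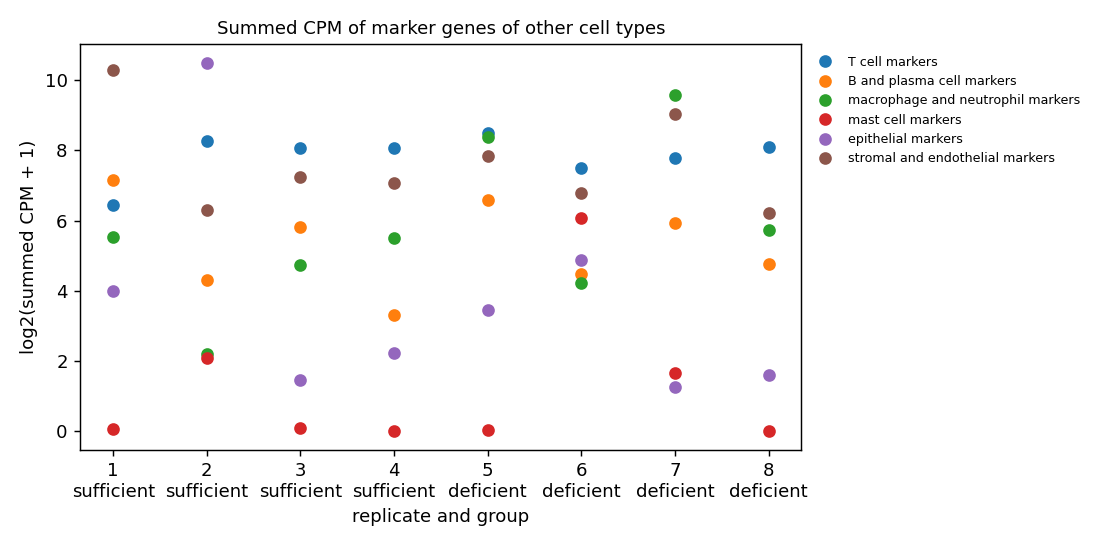
Summed CPM of the marker genes of 6 other cell types in each library, on a log2(summed CPM + 1) scale, 1 point per list and library. Epithelial markers reach 1438 CPM in sufficient replicate 2, stromal and endothelial markers 1249 CPM in sufficient replicate 1, and macrophage and neutrophil markers 762 CPM in deficient replicate 7.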

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

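The set of abundant genes and all tests on it (regrouping, the Malat1 covariate and libraries left out), and the tests of Il6 against fibroblast and macrophage transcripts, were chosen after the data were seen; the other regroupings were set before their results were. Libraries far from the other 3 of their group were found by the gap to the nearest library as a share of the group's range. Of 207 groups examined 17 stood out, where chance gives about 10.3, and 5 of them concerned sufficient replicate 1 and 4 deficient replicate 6.

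On the first principal component, sufficient replicate 1 lay at 166 against 6.1 to 25.7 for its group, and deficient replicate 6 at -188 against -14.7 to -1.6. On the second, deficient replicate 6 lay at 137 against -61.4 to -36.1. The TMM factor of sufficient replicate 1 was 1.02 against 0.946 to 0.956. This library also had the lowest sums of T cell markers, 86.3 CPM against 264 to 306, and of NK cell and ILC1 markers, 123 CPM against 554 to 632, and 103 CPM of Csf2 against 246 to 280. Deficient replicate 6 had 919 CPM summed over the genes near Zbtb46 against 515 to 555, and 187 CPM of Gmeb2 against 41.3 to 45.8. Sufficient replicate 2, the library with epithelial transcripts, had 15.4 CPM of Cd3d against 0, 15.2 CPM of Il5 against 0.757 to 0.939, and 36.7 CPM of Klrg1 against 0.0393 to 0.430. Sufficient replicate 4 had 1.22 CPM of Aasdh against 23.7 to 39.4, 592 CPM of S100a10 against 938 to 979, and 6.80 CPM of Lta against 51.3 to 73.6. Sufficient replicate 3 had 34.8 CPM of Sqle against 75.5 to 86.5, and deficient replicate 7 had 134 CPM of Dcn against 0.

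Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave 4 calls among genes with a mean of at least 100 CPM. The highest other split gave 0. The same held when each split took its highest count over all tested genes and over means of at least 50 and 100 CPM. For the number of calls in these sets the share of splits was thus under 0.05. The set was chosen after the data were seen and other counts were also regrouped, which that share does not cover, so chance is not excluded. For genes at an unadjusted p under 0.05 in the same set, 4 of the 35 splits gave at least the real 169 and the highest other gave 238. With Malat1 as a covariate the median absolute log2 fold of these 4 genes kept 99.0% of its size, while that of Lgals1 went from 1.84 to 1.63. This argues against the share of nuclear RNA as far as Malat1 alone tracks it. Leaving out replicate 1, 3 or 5 left 0 higher and 0 lower. Log2 folds were then 1.63 to 1.92 for Lgals1, -1.53 to -1.49 for Med31, -1.62 to -1.46 for Trmt61b and -1.24 to -1.15 for Snhg15. With all 8 libraries they were 1.84, -1.64, -1.51 and -1.29. Standard errors were 0.242 to 0.33 against 0.228 to 0.289 with all 8. The folds thus changed little, but the calls depended on which library was left out. Without replicate 6 the calls rose to 6 higher and 15 lower. Replicate 6 lay far from its group, so this setting cannot tell whether fewer libraries alone account for the loss. An effect of Zbtb46 loss on these genes may stay as a hypothesis, found and tested on the same libraries, and a part played by myeloid RNA in Lgals1 stays open: in the same gene order the log2 folds were 1.81, -1.54, -1.60 and -1.17 without replicates 1, 2 and 7, and 1.39, -1.48, -1.55 and -1.11 (standard errors 0.284 to 0.36) without replicates 5 and 7, the deficient libraries with most macrophage and neutrophil transcripts, with 0 calls in either setting.

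DESeq2 called 373 genes where edgeR called 0, but it tested 16714 genes against 8878, and 136 of its calls were among the genes edgeR tested. Of 24 splits drawn from the 35, 1 gave as many calls, the real one, but the highest other split gave 371. DESeq2 thus called nearly as many genes between mixed groups of the same mice, so the count itself says little about genotype, although the real split was formally the highest. By edgeR over all genes, for those at an unadjusted p under 0.05, 3 of the 35 gave as many as the real 364, with 440 the highest other, and for genes whose groups did not overlap, 2 of the 35 gave as many as the real 387, with 421 the highest other. The split with 440 and 421 placed replicate 6 with sufficient replicates 1, 2 and 4. The real counts of 0 genes by edgeR over all genes and 0 lists by camera are reached by 35 of the 35 splits whatever the data, so regrouping tests nothing there; the highest other split gave 0 genes and 4 lists.

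Il6 and Ift57 were nearly silent in sufficient and present in all deficient libraries. Counting genes with 3 counts or fewer in each library of one group and at least 10 CPM in each of the other, 14 of the 35 splits gave as many as the real 2, with 4 the highest other, so the number of such genes is no larger than regrouping gives. In deficient replicates 5, 6 and 8, Col1a1, Col1a2, Col3a1, Dcn and Sparc summed to at most 0.426% of the CPM of Il6. This argues against fibroblasts rich in these transcripts as the source there. The full stromal and endothelial list summed to 228, 109.6 and 74.0 CPM in these libraries. Other stromal or endothelial cells are therefore not excluded. In replicate 7 the same transcripts came to 716% of the CPM of Il6, so fibroblasts are not excluded there. In sufficient replicate 1, however, 839 CPM of these transcripts came with 0 counts of Il6. Macrophages, which the gate against CD11b should remove, are excluded in deficient replicates 5 and 6, where Lyz2, C1qa, C1qb, C1qc and Cd68 summed to 0.148 and 2.74 CPM beside 41.8 and 98.2 CPM of Il6 (CPM without TMM factors), at most 2.8% of it, and sufficient replicates 1, 3 and 4 had 34.1, 20.4 and 20.7 CPM of them with Il6 at 0 to 0.0343. Transcripts of other cells were there too. The neutrophil genes S100a8 and S100a9 had 238 and 94.1 CPM in replicate 5 and 316 and 359 in replicate 7. They had 4.14 and 3.42 in replicate 6 and 0.0939 and 0.188 in replicate 8. The mast cell gene Cpa3 had 66.2 CPM in replicate 6 against 0 in replicates 5, 7 and 8. Dendritic cell markers summed to 325.5 and 223.1 CPM in replicates 5 and 6. They summed to 169.1 and 145.4 CPM in replicates 7 and 8 and to 103.9 to 186.3 CPM in sufficient libraries. Of these markers Irf8 separated the groups and Ccl17 did not. These cells were not tested as a source of Il6. In deficient replicates 7 and 8 the sum of the macrophage genes was 72.2 and 21 CPM beside 60.3 and 18.9 of Il6, up to 120% of it. There macrophages cannot be told apart from ILC3s as the source, and chance stays open for the whole pattern.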

How the results depend on the processing

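Of the alternatives named here, the sets limited by mean CPM, edgeR with legacy = FALSE, the settings that left out several replicates, and all settings for the abundant set were chosen after the data were seen. Counts of 0 higher and 0 lower were also given by RLE, upper-quartile and no factors, limma-voom, robust edgeR, at least 5 CPM in at least 4 libraries, 1 surrogate variable, legacy = FALSE, and leaving out replicates 1 and 6 or 1, 2 and 7. DESeq2 gave 239 and 134, no filter 1 (Il6) and 1 (Med31), a mean of at least 100 CPM 1 and 3, and of at least 50 CPM 1 and 2. Without 1 library the counts were 0 higher and 0 to 2 lower, with 2 without replicate 6. The Zbtb46 log2 fold change kept its direction, at -5.19 to -3.66, with adjusted p of 0.379 to 0.986 except with DESeq2 (-4.30, adjusted p 0.0116). No alternative called a key gene. For lists, camera was run with ranks, an estimated correlation, RLE, at least 5 CPM in at least 4 libraries, each library left out, and without replicates 1 and 6 or 1, 2 and 7, and called 0 in each. Fry, run with all libraries, called 0 by its directional test and 1, glycolysis, for change in either direction (adjusted p 0.0277). Below a mean of 10 CPM 26.5% of values were at 3 counts or fewer, which limits those genes. The sex covariate was not run.

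In the abundant set, leaving out 1 library gave 0 to 6 higher and 0 to 15 lower. Both replicates 1 and 6 left out gave 5 and 12, replicates 1, 2 and 7 or replicates 5 and 7 left out 0 and 0, DESeq2 14 and 23, and limma-voom 7 and 16. With Malat1 as a covariate 5 were lower, and with the number of detected genes 1. In the latter setting Snhg15 and Trmt61b had log2 folds of -1.20 and -1.45, with an edgeR adjusted p of 0.0557 each. RLE and no factors gave 1 and 3, as did thinning, which moves genes of this abundance too little to test depth.

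Of 73 named genes with a log2 fold besides Zbtb46, none passed in the main test. Of 1527 pairs of gene and alternative, 1476 kept direction and side of the threshold, 22 passed it and 29 changed sign, as follows; the cause was not tested. With limma-voom Trac was -0.29, Lgals4 0.23, Car1 -3.74, Tnfsf11 -0.012 and Ccr6 -0.22. With 1 surrogate variable Car1 was -4.90. Without replicates 1 and 6 Ccna2 was -0.49, Igkc 0.24, Tnfsf11 -0.025 and Ccr6 -0.35, and without 1, 2 and 7 mt-Nd1 was -0.049, Lgals4 11.2 and Tnfsf11 -0.018. Leaving out 1 library moved Top2a from -0.94 to 4.50, Ccna2 from -0.052 to 2.79, Trac from -2.01 to 2.77, Klrg1 from -4.20 to 5.31, Jchain from -0.007 to 2.13, Lgals4 from -4.80 to 0.93, Car1 from -6.84 to 0.82, Tnfsf11 from -0.039 to 0.087, Csf2 from -0.12 to 0.41 and Ccr6 from -0.44 to 0.53.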

Other observations

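All lists, tests and settings in this part were chosen after the data were seen. More cytoskeletal and cortical genes had higher than lower fitted values in deficient ILC3s. A list for the actin cytoskeleton and its membrane cortex, called actin genes below for short, also held genes of other kinds such as Lgals1 and Vim. Of its 48 tested genes, 37 had higher fitted values and 11 lower, and 12 had higher values at an unadjusted p under 0.05 against 0 lower. Besides Lgals1 these included the intermediate filament gene Vim with 125 ± 35.7 against 350 ± 148 CPM, S100a6 with 360 ± 96.5 against 744 ± 171, the membrane-binding gene Anxa2 with 92.2 ± 28.5 against 264 ± 135, and the actin cross-linker gene Flna with 100 ± 14.9 against 252 ± 85.2 (mean ± SD over 4 libraries). In these 4 genes the groups did not overlap, and edgeR's adjusted p over all tested genes was 0.515 for each. Macrophage and neutrophil markers summed to 335 and 762 CPM in deficient replicates 5 and 7 against 17.8 and 52.6 CPM in replicates 6 and 8, and Lgals1, Vim, S100a6 and Anxa2 are also known from myeloid cells. In replicates 5 and 7 Lgals1 had 1150 and 853 CPM against 550 and 629 in 6 and 8, Vim 330 and 563 against 228 and 279, and S100a6 916 and 778 against 508 and 772, while Anxa2 had 456 and 142 against 214 and 246 and Flna 225 and 290 against 345 and 147. Without replicates 5 and 7, 30 of the 48 actin genes had higher fitted values. Ptgs2, encoding an inducible prostaglandin synthase, had 74.7 ± 30.6 against 240 ± 69.5 CPM, also without overlap.

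More splicing genes and genes induced by cyclic AMP had lower than higher fitted values. Of 27 tested splicing factors 21 had lower fitted values, and 17 without replicates 5 and 7, with Srek1 at 203 ± 42.6 against 72.0 ± 29.2 CPM and Clk4 at 666 ± 218 against 309 ± 116. Of 20 tested cyclic AMP and CREB responsive genes 16 had lower fitted values, and 14 without replicates 5 and 7, with Crem at 8038 ± 1036 against 4609 ± 1018 CPM, Gem at 3237 ± 311 against 1926 ± 358, Coq10b at 723 ± 227 against 356 ± 14.1 and Rrad at 183 ± 118 against 38.5 ± 18.5. Areg and Ptgs2 belong to the same list and went the other way.

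These lists were drawn up around genes already seen at a small p, so no p over them is independent evidence that a group moved as a whole. Over each whole list the mean log2 CPM differed by 0.58 for the actin genes (exact two-sided permutation p of 0.0857), by -0.39 for the splicing factors (exact p of 0.114) and by -0.10 for the cyclic AMP genes (exact p of 0.4). Over only the members above an unadjusted p of 0.05 both among all tested genes and among those with a mean of at least 100 CPM it was 0.41 for 35 actin genes (exact p of 0.2), -0.10 for 20 splicing factors (exact p of 0.629) and 0.14, the opposite direction, for 11 cyclic AMP genes (exact p of 0.514). Leaving out members by their own p pulls these values toward or past 0, so they decide neither for nor against a group change. Camera gave a p of 0.000124 for the actin and 4.51e-05 for the splicing list with its preset correlation, and p values of 0.131 and 0.193 with an estimated one. For the cyclic AMP list those values were 0.0165 and 0.0399, and the 4 nuclear noncoding RNAs had 0.27 and 0.476. Without deficient replicates 5 and 7 the camera p with the preset correlation was 0.0737 for the actin, 0.126 for the splicing and 0.181 for the cyclic AMP list. Without replicates 1, 2 and 7 it was 0.013, 0.00573 and 0.149, with 37 of 48 actin genes higher and 22 of 27 splicing factors and 13 of 20 cyclic AMP genes lower. With an estimated correlation the camera p in that setting was 0.406, 0.441 and 0.285, and without replicates 5 and 7 it was 0.409, 0.587 and 0.232.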
